A study of Mus musculus with 8 samples.

How the data were processed

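Total RNA of the cerebral cortex of 8 mouse libraries was sequenced by the authors, 4 from tamoxifen-treated Tak1 floxed controls and 4 from Tak1 floxed mice with Cdh5-CreER. Per the submitters' processing notes, reads were checked with FastQC, aligned to GRCm38 with HISAT or HISAT2, counted per gene with featureCounts and compared with DESeq2, all without a version. The label of the library kit names a kit for ChIP sequencing, and whether the counting used strand is not stated. The labels do not say that each library is a separate mouse, so p-values measure the spread between these libraries. The knockout columns carry the numbers 2 to 5 in the deposited table, while the sample titles number the knockouts 5 to 8.

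The counts per gene and library are whole numbers as deposited by the authors, without normalization. The deposited mean signal per gene is the authors' DESeq2 mean of counts divided by size factors. The deposited log2 fold change and its error are the authors' DESeq2 values for knockout over control. The deposited score is the authors' log2 fold change divided by its standard error. The deposited p-value columns hold the authors' unadjusted and adjusted p values. Of 29012 lines, 280 were repeats and were removed, which left 28732 genes, and 28682 gene IDs were matched to GENCODE release M21 for symbols and positions.

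Genes were kept with edgeR's filterByExpr (13168 removed, 15564 kept), scaled by TMM and tested with edgeR's quasi-likelihood F test (robust) with Benjamini-Hochberg adjustment at 0.05. No covariate was used. CPM are TMM-scaled, given as mean ± SD, and log2 fold changes are given with the standard error. In total 40 gene lists were fixed before the data were examined, and 39 with at least 5 tested members were tested 2-sided with limma camera at a preset correlation of 0.01. Of the listed genes, 2 were matched through another symbol. Single-value comparisons used exact permutation tests over 70 arrangements, whose smallest 2-sided p is 0.0286. Principal components used log2 CPM with a prior count of 2. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

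The genes named were chosen by a rule written before the data were examined. It takes Map3k7 and Cdh5, and the 12 largest changes in each direction among genes that passed, had a mean of at least 1 CPM and did not overlap between groups, leaving out models without an assigned name. It also takes up to 4 members of each list by smallest p, or up to 6 for a list that passed. Ttr, Arc, Nr4a3, Egr1, Fos, Fosb, Nptx2, Cx3cr1, Gfap, Vegfa, Kdr, Pecam1, Itm2a, Tnfrsf11b, P4ha1, Emp1, Ermn, Sox10, Folr1, Gm42418, mt-Rnr1 and the clock genes Dbp, Ciart and Hlf were chosen after their values were seen. A gene that the rule takes is not reported here.

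Alternatives tried were DESeq2 size factors and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries, DESeq2, limma voom, leaving out each library, an adjusted p of 0.1, a test against a 1.2-fold change, and for lists an estimated correlation, fry, an exact permutation test and the removal of genes in more than 1 list. Removal of a trend on GC content and length, and the column number as a replicate block, were chosen after seeing the data. The procedure was tested on simulated data. Of 200 genes changed among 15319, it recovered 25.4% at 1.5-fold, 68.7% at 2-fold and 93.9% at 4-fold, and 7.14% of its calls were false. A simulated list of 20 further genes moved 1.5-fold had a camera p of 2.33e-23 and one not moved 0.581. Simulated genes were drawn independently, while the estimated correlation was 0.47 in the glucocorticoid list and 0.58 in the mitochondrially encoded list. The simulation therefore does not check camera at the preset correlation of 0.01. Depth was 13483354 to 17728963 counts per library, and read-level data were not used here.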

Results

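RNA was measured in the cerebral cortex of adult mice in which the kinase TAK1, encoded by Map3k7, can be deleted from endothelial cells, the cells that line blood vessels. The knockout mice carried floxed Tak1 alleles together with Cdh5-CreER, a tamoxifen-inducible recombinase driven by the promoter of the endothelial cadherin gene. Control mice carried the floxed alleles without the recombinase, and both groups were given tamoxifen. There were 4 control and 4 knockout libraries, at postnatal day 90 per the sample labels and at 12 to 14 weeks per the series text. Libraries are named here by group and by the number in the deposited table, 1 to 4 for controls and 2 to 5 for knockouts. Each library held between 13483354 and 17728963 counts assigned to genes, and 15564 genes passed the expression filter. The series text names differential expression and gene set analysis of knockouts against littermate controls, and its title concerns neuronal activity after the loss of vessels.

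Map3k7 (ENSMUSG00000028284, chromosome 4, 31964097 to 32023467, GRCm38) did not pass, and its levels overlapped between the groups. Its level was 40.02 ± 2.89 CPM in controls and 38.8 ± 3.16 CPM in knockouts (mean ± SD, n = 4 each). The single libraries ranged from 36.2 to 42.7 CPM in controls and from 35.3 to 42.6 CPM in knockouts. The log2 fold change was -0.04 ± 0.11 (SE), with an adjusted p of 0.843 in edgeR's quasi-likelihood test. The RNA came from whole cortex, where other cells also express the gene, and the counts cover the whole gene and not the floxed part, so this level does not check the deletion. Cdh5 (chromosome 8, 104101625 to 104144511), whose promoter drives the recombinase, rose by 0.98 ± 0.24 (log2 ± SE, adjusted p = 0.0377). It stood at 10.2 ± 0.949 CPM in controls and at 25.5, 16.8, 11.1 and 27.4 CPM in knockouts 2, 3, 4 and 5, so that knockout 4 lay within the control range of 9.28 to 11.3. Cdh5 did not pass without control 1, 2, 3 or 4 (adjusted p 0.110, 0.121, 0.0746 and 0.0567), without knockout 2 or 5 (0.0998 and 0.114), or in limma voom (0.0695), and its adjusted p over the alternatives ran from 0.00133 to 0.281.

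Lcn2 (chromosome 2, 32384633 to 32388252), which encodes the siderophore-binding acute-phase protein lipocalin 2, rose by 4.87 ± 0.56 on the log2 scale, from 0.336 ± 0.305 to 9.65 ± 3.87 CPM (SD, n = 4 each, adjusted p = 0.00333). Other named genes among the 12 largest rises were the lipid droplet coat gene Plin4 (2.80 ± 0.30), the cell cycle inhibitor Cdkn1a (2.91 ± 0.41), the metallothionein Mt2 (2.70 ± 0.41), the transcription factor Cebpd (2.62 ± 0.45) and the bicarbonate transporter Slc4a5 (3.28 ± 0.74), which is also a member of the choroid plexus and ependyma list. The others were Shox2 (4.71), Ctla2a (3.49), the sodium channel gene Scn10a (3.34), Snord87 (3.12), Chn1os3 (2.94) and Tmem252 (2.72), with adjusted p between 0.00381 and 0.0279 in edgeR. Chn1os3 is antisense to Chn1, and because it is not stated whether the counting used strand, its reads cannot be told apart from those of Chn1 where they overlap. Snord87 is a small nucleolar RNA gene. Slc4a5 did not pass in the authors' DESeq2 results (3.30 ± 1.27, adjusted p = 0.0726) and lost its call in 9 of 16 alternatives.

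The largest fall among named genes was that of Akr1c14, a hydroxysteroid dehydrogenase gene (chromosome 13, 4049011 to 4090688), which fell by 2.55 (SE 0.45, adjusted p = 0.00999), from 2.63 ± 0.855 to 0.427 ± 0.294 CPM. The interferon-induced genes Gbp5 (-1.75 ± 0.25) and Oasl2 (-1.42 ± 0.35), the neuronal activity gene Npas4 (-1.50 ± 0.34) and the dendritic cell transcription factor Batf3 (-1.54 ± 0.36) were also among the 12. Tmem40 (-1.78), Fam228a (-1.68), Zfp493 (-1.61), Zbtb3 (-1.44), Ppp1r35 (-1.39), Ifrd2 (-1.39) and Myom3 (-1.36) completed the set, with adjusted p between 0.00438 and 0.0467 in edgeR. All 4 knockout values of each of these genes lay on the same side of all 4 control values, which was a condition of the rule that chose them. Most of them stood at a few CPM, where a fold rests on few reads per library.

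In total 1001 of the 15564 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 535 higher and 466 lower in knockouts. Of these, 189 were more than 2-fold higher and 59 more than 2-fold lower, and 94 were gene models without an assigned name (47 in each direction). The groups did not overlap in 951 of the 1001 genes, a feature that passing the test itself favours. Among all tested genes the share without overlap was 16.2%, against 2.86% given by chance. The counts depended on single libraries. They were 208 higher and 117 lower without control 1, 93 and 35 without control 2, 257 and 210 without control 3, 224 and 146 without knockout 2, 109 and 46 without knockout 5, and 1012 and 1043 without knockout 4. Across all 8 such fits 112 of the 1001 genes passed each time, 78 of them higher and 34 lower. They include Lcn2, Shox2, Scn10a, Cdkn1a, Plin4, Tmem252, Mt2, Gbp5, Tek, Adgrl4, Slc2a1, Mfsd2a, Hif3a, Ddit4, Inhba, Ier5, Rspo2, Gjb6, Steap4, Enpp2, Clic6, Sgk1, Tsc22d3, Pdk4, Klf9 and mt-Rnr1, which are the 26 named here that did so. Every other gene said here to have risen or fallen lost its call without at least 1 library, most often control 2 or knockout 5, and each kept its sign. DESeq2 on the same counts called 912 genes higher and 854 lower.

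**Figure D1:**
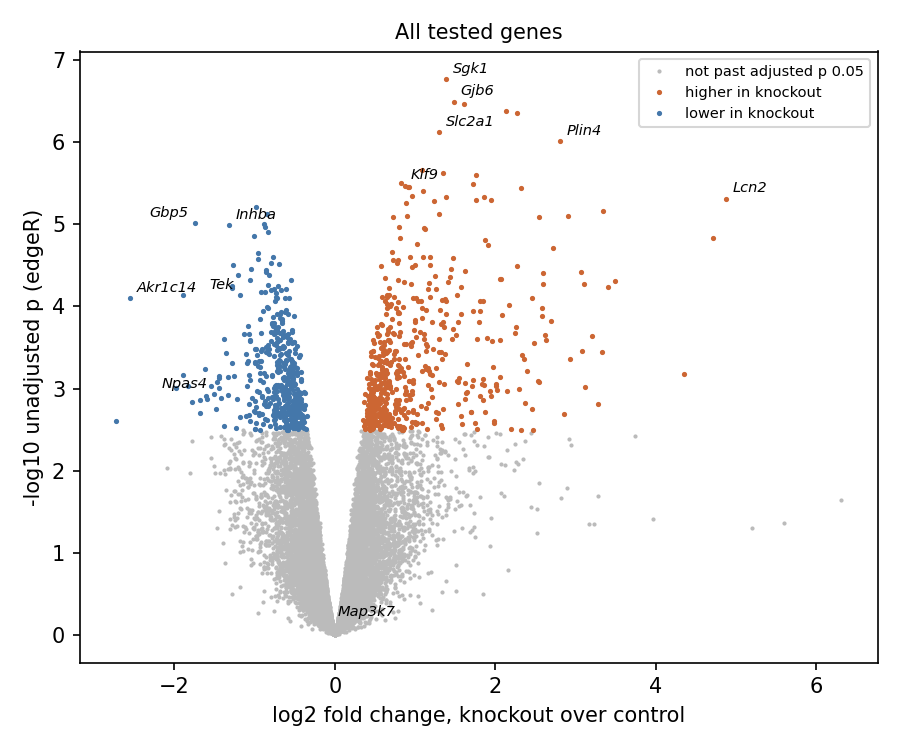
Each point is 1 of 15564 tested genes, with the log2 fold change of knockout over control on the horizontal axis and -log10 of the unadjusted edgeR p on the vertical axis. Orange points are the 535 genes higher and blue points the 466 genes lower in knockouts at an adjusted p of 0.05, and Map3k7 lies near 0 on both axes.

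Genes induced by glucocorticoid hormones rose together. Of 19 tested members of this list, 17 rose, none fell and 2 did not pass, with a median log2 fold change of 1.45. The kinase gene Sgk1 rose from 46.1 ± 9.79 to 121 ± 6.65 CPM (1.39 ± 0.14, adjusted p = 0.00138). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, rose by 1.09 ± 0.14, the transcription factor Klf9 by 0.87 ± 0.11, the pyruvate dehydrogenase kinase Pdk4 by 1.34 ± 0.17 and Hif3a by 1.76 ± 0.22, each with an edgeR adjusted p of 0.00333. Every knockout library, knockout 4 included, lay above every control for these 5 genes. 18 members rose, adjusted over the list alone. The list was higher in limma's camera test (adjusted p = 2.73e-42), and had an adjusted p = 0.0708 with an estimated correlation and 1.16e-61 to 0.101 over all alternatives. The upper end, 0.101, is the smallest adjusted p that the exact permutation test gave for any list. Without the genes shared with other lists, camera gave an adjusted p of 1.02e-29.

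**Figure D2:**
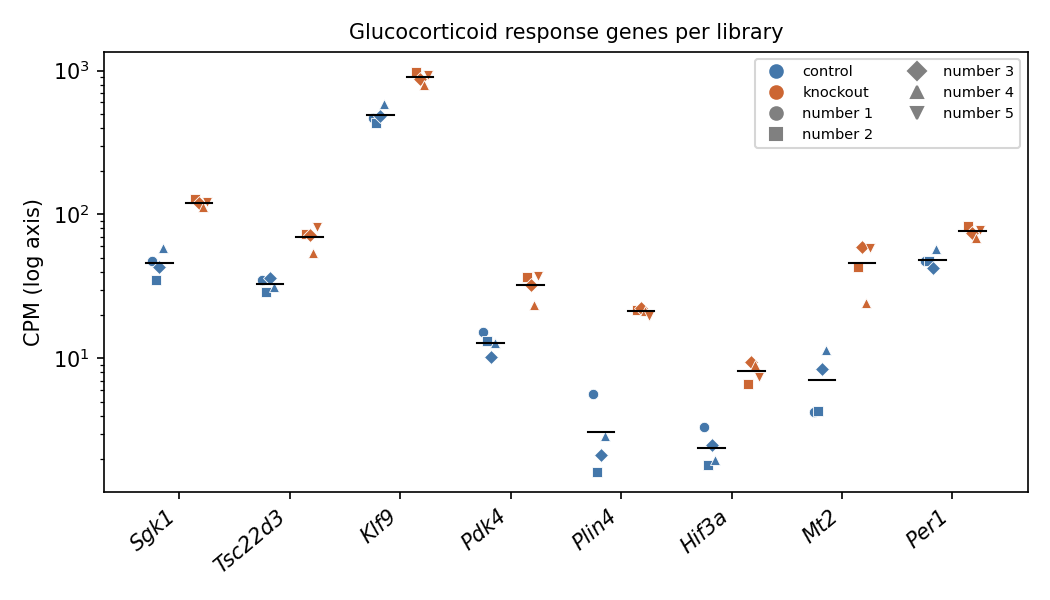
CPM on a log axis for 8 glucocorticoid response genes in each control (blue) and knockout (orange) library, with marker shapes for the library number and black lines for the group means of 4. For each gene all knockouts lie above all controls, for example from 113 to 129 CPM against 35.2 to 58.7 CPM for Sgk1.

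Endothelial genes moved in both directions. Of 29 tested endothelial markers, 6 rose, 2 fell and 21 did not pass, with a median of 0.25. Besides Cdh5, the adhesion receptor gene Adgrl4 (1.04 ± 0.19), the sialomucin gene Cd34 (0.80 ± 0.15), Cd93 (1.12 ± 0.24), the clotting protein gene Vwf (0.98 ± 0.22) and Ly6c1 (1.31 ± 0.24) rose, with adjusted p between 0.0101 and 0.0256. Tek, which encodes the angiopoietin receptor, fell from 14.8 ± 3.27 to 6.50 ± 1.72 CPM (-1.18 ± 0.21, adjusted p = 0.00999), and Itm2a, named after its value was seen, fell to a log2 fold change of -0.76 ± 0.20. Pecam1 (0.35 ± 0.18, adjusted p = 0.248) and the VEGF receptor gene Kdr (0.06 ± 0.19, adjusted p = 0.873), also chosen after their values were seen, did not pass. 9 members rose and 2 fell, adjusted over the list alone. The endothelial cells list had a camera adjusted p of 0.00533, and an adjusted p = 0.577 with an estimated correlation and 4.29e-05 to 0.577 over all alternatives. Its mean was 2.63 log2 CPM in knockout 3, against 2.64 to 2.77 in controls and 3.00 to 3.16 in the other knockouts. Without knockout 3 the median was 0.38.

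Among blood-brain barrier genes 3 of 21 rose and none fell. The glucose transporter Slc2a1 rose from 42.9 ± 2.59 to 106 ± 24.5 CPM (1.30 ± 0.15, adjusted p = 0.00194), the lipid transporter Mfsd2a by 1.10 ± 0.15 (adjusted p = 0.00333) and Itih5 by 0.77 ± 0.14 (adjusted p = 0.0114). The list as a whole did not pass camera (adjusted p = 0.129, 0.0389 without knockout 3), and adjusted over the list alone 3 members rose. Of 13 genes of endothelial activation and leak, 6 rose and 1 fell, with a median of 1.14. Lcn2, Ctla2a, Vwf, the interleukin 1 receptor gene Il1r1 (1.16 ± 0.20, adjusted p = 0.00946), the angiopoietin gene Angpt2 (1.79 ± 0.34, adjusted p = 0.0135) and the endothelin gene Edn1 (1.65 ± 0.36, adjusted p = 0.0209) rose. Tnfrsf11b, named after its value was seen, had a log2 fold change of -0.87 ± 0.22 (adjusted p = 0.0335). Edn1 was at 1.35 CPM in knockout 4, within the control range of 0.791 to 1.38 CPM. 8 rose and 1 fell, adjusted over the list alone. The endothelial activation and leak list had a camera adjusted p of 2.08e-06, which became 0.153 without genes that stand in other lists, and an adjusted p = 0.170 with an estimated correlation and 5.90e-09 to 0.170 over all alternatives.

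**Figure D3:**
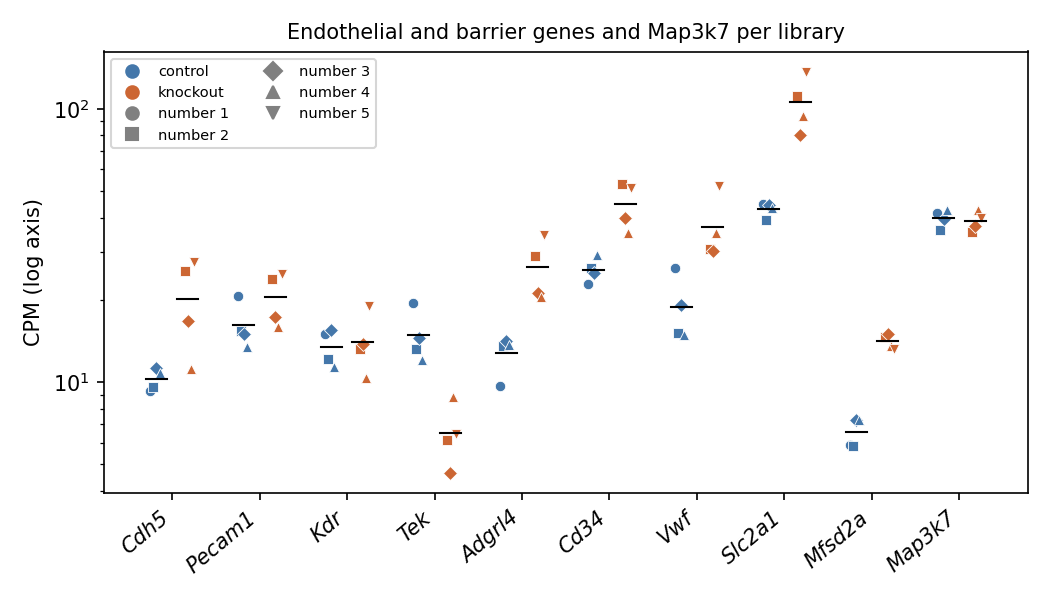
CPM on a log axis for endothelial and barrier genes and Map3k7 in each control (blue) and knockout (orange) library, with marker shapes for the library number and black lines for the group means of 4. Slc2a1 and Mfsd2a are higher in every knockout than in every control, Tek is lower, and Map3k7 overlaps between the groups.

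Of 28 hypoxia response genes, 6 rose, 1 fell and 21 did not pass, with a median of 0.25. The risers were Slc2a1, Hif3a, the mTOR inhibitor gene Ddit4 (1.45 ± 0.23, adjusted p = 0.00790), Bnip3 (0.62 ± 0.15, adjusted p = 0.0283), adrenomedullin, Adm (1.84 ± 0.44, adjusted p = 0.0332), and the lactate dehydrogenase gene Ldha (0.59 ± 0.15, adjusted p = 0.0382). The collagen prolyl hydroxylase gene P4ha1, named after its value was seen, fell to -0.48 ± 0.13 (adjusted p = 0.0483). Vegfa, the main hypoxia-induced vessel growth factor and likewise named after its value was seen, was at 47.4 ± 8.46 CPM in controls and 50.8 ± 16.7 CPM in knockouts (adjusted p = 0.833). Hif3a and Ddit4 also belong to the glucocorticoid list. 8 hypoxia genes rose and 2 fell, adjusted over the list alone. The hypoxia response list had a camera adjusted p of 3.90e-04, which became 0.281 without genes in more than 1 list, and an adjusted p = 0.170 with an estimated correlation and 3.75e-05 to 0.281 over all alternatives. Of 19 glycolysis genes, 3 rose and none fell: Ldha, Ldhb (0.41 ± 0.11, adjusted p = 0.0406) and Gapdh (0.93 ± 0.23, adjusted p = 0.0326). Gapdh stood at only 8.72 ± 3.12 CPM in controls, and as a gene with many processed pseudogenes it is uncertain here. 5 glycolysis genes rose, adjusted over the list alone. The list had a camera adjusted p of 0.0190, 0.0775 without knockout 5 and 0.217 without genes in more than 1 list, and an adjusted p = 0.522 with an estimated correlation and 0.00468 to 0.522 over all alternatives.

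Genes of sprouting vessels, of the vessel wall matrix and of mural cells did not pass as lists. Of 22 tip cell and angiogenesis genes, 2 rose (Angpt2 and Adm) and none fell (camera adjusted p = 0.414). 3 rose and 3 fell, adjusted over the list alone. Of 21 basement membrane and matrix genes, 2 rose, the protease inhibitor Timp3 (0.53 ± 0.12, adjusted p = 0.0240) and Sparc (0.45 ± 0.11, adjusted p = 0.0368), and none fell (camera adjusted p = 0.153, 0.0273 without knockout 3 and 0.0462 without knockout 4). 4 rose and 1 fell, adjusted over the list alone. Of 17 pericyte and smooth muscle genes, none rose and the myosin light chain gene Myl9 fell (-0.71 ± 0.18, adjusted p = 0.0351, camera adjusted p = 0.234). 2 fell, adjusted over the list alone.

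Among genes that neurons switch on with activity, some fell and others rose. Of 39 immediate early genes, 3 rose, 3 fell and 33 did not pass, with a median of -0.18 (-0.32 without knockout 4 and -0.12 without knockout 3). Inhba, which encodes an activin subunit, fell from 24.5 ± 1.51 to 9.84 ± 3.07 CPM (-1.31 ± 0.19, adjusted p = 0.00438). Ier5 (-1.04 ± 0.17, adjusted p = 0.00790) and Npas4 also fell. The 3 risers were Per1 (0.65 ± 0.12, adjusted p = 0.00999), which is also a glucocorticoid target, Maff (2.58 ± 0.45, adjusted p = 0.0114) and Klf4 (0.85 ± 0.22, adjusted p = 0.0370). Several well-known activity genes, chosen here after their values were seen, differed strongly between knockout libraries. Arc was at 111 to 162 CPM in controls and at 30.5, 16.6, 135 and 32.7 CPM in knockouts 2 to 5 (adjusted p = 0.248). Nr4a3 was at 58.7 to 74.9 CPM in controls and at 16.2, 10.9, 54.4 and 12.4 CPM in knockouts (adjusted p = 0.151). The same held for Egr1, at 183 CPM in knockout 4 and 36.5 to 88.8 CPM in the other knockouts (adjusted p = 0.410), while Fos (-0.36 ± 0.29, adjusted p = 0.476), Fosb (-0.79 ± 0.28, adjusted p = 0.102) and Nptx2 (-0.94 ± 0.25, adjusted p = 0.0559) did not pass. Without knockout 4, Arc (-2.39 ± 0.24, adjusted p = 5.73e-04), Nr4a3 (-2.27 ± 0.16, adjusted p = 7.98e-06), Egr1 (-1.17 ± 0.26, adjusted p = 0.0215), Fosb (-1.13 ± 0.22, adjusted p = 0.00537) and Nptx2 (-1.19 ± 0.20, adjusted p = 0.00527) passed while Fos did not (adjusted p = 0.220), and 14 members fell and 4 rose. Arc, Nr4a3, Egr1, Fosb and Nptx2 and this fit were picked after the values of knockout 4 were seen. Their p-values without knockout 4 are therefore not independent evidence of a fall. With all libraries 6 members of the list rose and 8 fell, adjusted over the list alone. The list's camera adjusted p was 0.0486, with an adjusted p = 0.706 with an estimated correlation and 9.44e-07 to 0.706 over all alternatives. That list stood at 9.44e-07 without knockout 4 and above 0.05 without control 2 (0.0667), control 4 (0.0972), knockout 2 (0.0534), knockout 3 (0.334) or knockout 5 (0.0775).

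**Figure D4:**
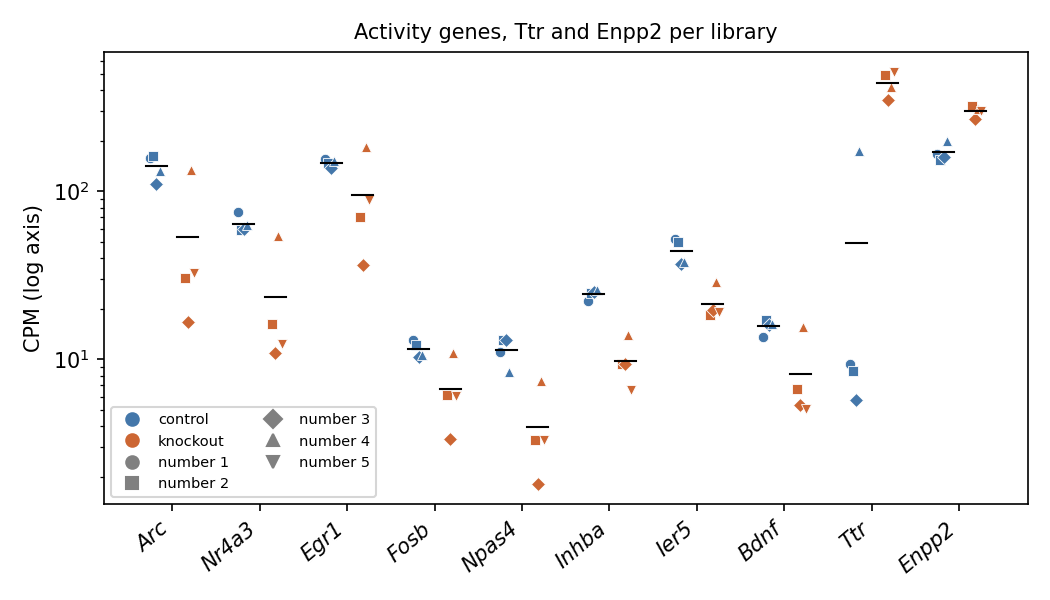
CPM on a log axis for activity genes and for Ttr and Enpp2 in each control (blue) and knockout (orange) library, with marker shapes for the library number and black lines for the group means of 4. Knockout 4 lies within the control range for Arc and Bdnf, just below it for Nr4a3, and apart from the other knockouts for Ier5, and control 4 has 174 CPM of Ttr against 5.74 to 9.35 CPM in the other controls.

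Of 21 neuropeptide and secreted factor genes, 2 fell and none rose. They were the Wnt agonist Rspo2 (-0.96 ± 0.15, adjusted p = 0.00687) and the neurosecretory gene Vgf (-0.84 ± 0.17, adjusted p = 0.0167). The growth factor gene Bdnf was at 15.8 ± 1.55 CPM in controls and at 6.71, 5.39, 15.6 and 5.09 CPM in knockouts 2 to 5 (adjusted p = 0.102), and without knockout 4 it fell (-1.45 ± 0.17, adjusted p = 2.83e-04). That fit was likewise picked after the value of knockout 4 was seen, so its p-value is not independent evidence. 3 fell, adjusted over the list alone. The neuropeptides and secreted trophic factors list had a camera adjusted p of 0.0427, 0.107 without control 2, 0.0717 without knockout 2 and 0.125 without knockout 3, and an adjusted p = 0.506 with an estimated correlation and 0.00468 to 0.506 over all alternatives.

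Lists of neuron types and of synaptic and channel proteins did not pass. Of 25 excitatory neuron genes, the transcription factor gene Neurod6 fell (-0.68 ± 0.14, adjusted p = 0.0186) and none rose, and of 24 inhibitory neuron genes none passed (camera adjusted p = 0.766 and 0.414). The median of the excitatory list was 0.04 while its mean was -0.0067 and its camera direction was down. 1 excitatory gene rose and 2 fell, and 0 of the inhibitory genes passed, adjusted over the list alone. Of 28 synapse genes, the vesicle priming gene Unc13a fell (-0.42 ± 0.10, adjusted p = 0.0344) and none rose (camera adjusted p = 0.293, 1 fall adjusted over the list alone). Of 36 neurotransmitter receptor genes, the glutamate receptor Gria4 (-0.49 ± 0.10, adjusted p = 0.0182) and the muscarinic receptor Chrm1 (-0.59 ± 0.14, adjusted p = 0.0302) fell and the nicotinic receptor Chrnb2 (0.46 ± 0.11, adjusted p = 0.0266) rose (camera adjusted p = 0.234, 0.0389 without knockout 3, 2 up and 2 down adjusted over the list alone). Of 30 ion channel genes, the potassium channel Kcna4 (-0.72 ± 0.15, adjusted p = 0.0178) and the calcium channel Cacna1g (-0.49 ± 0.13, adjusted p = 0.0465) fell and Kcna1 (0.48 ± 0.10, adjusted p = 0.0178) rose (camera adjusted p = 0.4004, 1 up and 2 down adjusted over the list alone). The median of the ion channel list changes sign with the scaling.

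Astrocyte genes changed in both directions. Of 20 astrocyte markers, the gap junction gene Gjb6 rose from 12.9 ± 2.15 to 36.1 ± 5.51 CPM (1.49 ± 0.16, adjusted p = 0.00138) and the folate enzyme gene Aldh1l1 rose (0.60 ± 0.13, adjusted p = 0.0227), while the amino acid transporter Slc7a10 fell (-0.76 ± 0.14, adjusted p = 0.0135). 4 rose and 2 fell, adjusted over the list alone. The astrocytes list had a camera adjusted p of 0.0438, lost without control 1 (0.0648), control 2 (0.0667), control 4 (0.0800) or knockout 2 (0.0841), and an adjusted p = 0.288 with an estimated correlation and 0.0139 to 0.288 over all alternatives. Of 25 reactive astrocyte genes, 7 rose and none fell, with a median of 0.45. They were Lcn2, Steap4 (3.10 ± 0.53, adjusted p = 0.00915), the cytokine receptor Osmr (1.35 ± 0.26, adjusted p = 0.0135), ceruloplasmin, Cp (0.63 ± 0.14, adjusted p = 0.0205), Cd109 (1.34 ± 0.34, adjusted p = 0.0373), Srgn (1.03 ± 0.27, adjusted p = 0.0398) and, outside the naming rule, Emp1 (2.32 ± 0.60, adjusted p = 0.0496). The intermediate filament gene Gfap, chosen after its value was seen, was at 90.5 ± 29.0 CPM in controls and 120.3 ± 80.1 CPM in knockouts (adjusted p = 0.637). 11 rose and 1 fell, adjusted over the list alone. The camera adjusted p was 3.47e-05, with an adjusted p = 0.347 with an estimated correlation and 6.40e-08 to 0.347 over all alternatives.

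Of 19 genes of homeostatic microglia, the complement genes C1qa (1.16 ± 0.27, adjusted p = 0.0273) and C1qb (0.98 ± 0.23, adjusted p = 0.0265) and the phagocytic receptor Mertk (0.49 ± 0.11, adjusted p = 0.0258) rose, and the transcription factor Sall1 fell (-0.92 ± 0.20, adjusted p = 0.0204). The fractalkine receptor gene Cx3cr1, chosen after its value was seen, was at 59.6 ± 7.58 CPM in controls and at 25.4, 7.97, 48.9 and 17.0 CPM in knockouts 2 to 5 (adjusted p = 0.164, and 0.0176 without knockout 4). For Cx3cr1 the fit without knockout 4 was also picked after its value was seen. The list did not pass (camera adjusted p = 0.239, 0.0322 without knockout 2 and 0.0368 without knockout 4). 3 rose and 3 fell, adjusted over the list alone. Of 18 activated microglia genes only the lysosomal protease gene Ctsd rose (0.81 ± 0.18, adjusted p = 0.0233), also adjusted over the list alone. The activated microglia list had a camera adjusted p of 0.0486, which was above 0.05 without control 1 (0.0547), control 4 (0.0972), knockout 2 (0.160) or knockout 4 (0.0672), and an adjusted p = 0.347 with an estimated correlation and 0.00916 to 0.347 over all alternatives.

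Of 18 oligodendrocyte genes, 4 rose and 2 fell. The myelin transcription factor Myrf (0.71 ± 0.13, adjusted p = 0.0131), Mal (0.80 ± 0.17, adjusted p = 0.0215), Cldn11 (0.59 ± 0.13, adjusted p = 0.0229) and Mobp (0.89 ± 0.21, adjusted p = 0.0330) rose. Ermn (-0.62 ± 0.16, adjusted p = 0.0358) and Sox10 (-0.81 ± 0.22, adjusted p = 0.0470), both named after their values were seen, fell. 6 rose and 4 fell, adjusted over the list alone (camera adjusted p = 0.535). None of 14 oligodendrocyte precursor genes passed over all genes, while 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.873).

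Interferon response genes fell where they changed. Of 22 tested members, Gbp5, Oasl2 and Gbp3 (5.33 ± 1.66 to 2.68 ± 0.861 CPM, adjusted p = 0.0490) fell and none rose, and 3 fell adjusted over the list alone. The interferon response list had a camera adjusted p of 0.0106, and an adjusted p = 0.155 with an estimated correlation and 9.05e-04 to 0.155 over all alternatives. NF-kB target and inflammation genes rose where they changed. Of 17 tested members 4 rose, the inhibitor gene Nfkbia (0.85 ± 0.16, adjusted p = 0.0113), the cytokine signal suppressor Socs3 (1.72 ± 0.32, adjusted p = 0.0118), Cebpd and Il1r1, and 9 rose adjusted over the list alone. Nfkbia also stands in the glucocorticoid list. The camera adjusted p was 4.57e-04, 0.0585 without genes in more than 1 list, with an adjusted p = 0.121 with an estimated correlation and 2.83e-05 to 0.121 over all alternatives. Of 26 TAK1 pathway genes only Il1r1 rose, also adjusted over the list alone, and none fell (camera adjusted p = 0.664). The median of that list changes sign with the scaling and had another sign than its mean of 0.06. Of 23 cell death genes, Cdkn1a, Pmaip1 (1.13 ± 0.23, adjusted p = 0.0164) and the death receptor gene Fas (1.26 ± 0.33, adjusted p = 0.0389) rose and the survival gene Bcl2 fell (-0.53 ± 0.15, adjusted p = 0.0485, camera adjusted p = 0.266), with 3 up and 1 down adjusted over the list alone. Of 21 listed antigen presentation genes 14 had no counts used here and 5 were tested, so the list covers little of that process. None of the 5 passed (camera adjusted p = 0.414), and 1 rose adjusted over the list alone.

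Markers of tissues and cells next to the cortex were also measured. Choroid plexus genes rose, with 7 of 16 members of the choroid plexus and ependyma list higher and none lower, at a median of 1.26. The phospholipase gene Enpp2 rose by 0.82 ± 0.11 (adjusted p = 0.00333), Clic6 by 1.23 ± 0.17 (adjusted p = 0.00333), F5 by 1.81 ± 0.31 (adjusted p = 0.0101), Otx2 by 2.26 ± 0.44 (adjusted p = 0.0143) and Sostdc1 by 1.30 ± 0.27 (adjusted p = 0.0180). The other risers were Slc4a5 and, chosen after its value was seen, Folr1 (1.98 ± 0.53, adjusted p = 0.0450). Slc4a5 did not pass in the authors' DESeq2 results (adjusted p = 0.0726). The transthyretin gene Ttr (chromosome 18, 20665280 to 20674321), chosen after its values were seen, was at 9.35, 8.54, 5.74 and 174 CPM in controls 1 to 4 and at 496, 351, 418 and 513 CPM in knockouts 2 to 5, with an adjusted p of 0.183 in edgeR. 10 rose, adjusted over the list alone. The choroid plexus and ependyma list had a camera adjusted p of 4.37e-11, and an adjusted p = 0.0708 with an estimated correlation and 4.40e-25 to 0.101 over all alternatives. Here too 0.101 is the smallest adjusted p that the exact permutation test gave. Of 22 fibroblast genes of the vessel and meningeal coverings, Slc6a20a (1.14 ± 0.21, adjusted p = 0.0116), Ptgds (0.56 ± 0.13, adjusted p = 0.0254) and Mgp (0.96 ± 0.23, adjusted p = 0.0305) rose and none fell, also adjusted over the list alone. That list's median was -0.11, its mean -0.0026 and its camera direction up (adjusted p = 0.869).

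Of 24 listed leukocyte and border macrophage genes 7 had no counts used here and 7 were tested, none of which passed over all genes. The neutrophil gene S100a9 was at 0.715 ± 0.702 CPM in controls and at 13.4, 10.9, 1.17 and 12.1 CPM in knockouts 2 to 5 (adjusted p = 0.0536). 2 rose, adjusted over the list alone. The blood leukocytes and border macrophages list had a camera adjusted p of 0.00533, and an adjusted p = 0.347 with an estimated correlation and 2.92e-06 to 0.347 over all alternatives. None of 8 red blood cell genes passed (camera adjusted p = 0.562), and 1 fell adjusted over the list alone. Of 15 striatum genes Syndig1l fell (-0.52 ± 0.13, adjusted p = 0.0369, camera adjusted p = 0.266), also adjusted over the list alone. Of 16 thalamus and hippocampus genes Rora rose (0.46 ± 0.11, adjusted p = 0.0305, camera adjusted p = 0.572), with 2 up and 1 down adjusted over the list alone, and the sign of its median changes with the scaling.

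Of 8 mitochondrially encoded protein genes none passed over all genes and 1 rose adjusted over the list alone. The complex I gene mt-Nd5 was at 3205 ± 687 CPM in controls and 6190.3 ± 2132 CPM in knockouts (adjusted p = 0.0589). The mitochondrially encoded genes list had a camera adjusted p of 0.0126, 0.0637 without knockout 2, and an adjusted p = 0.577 with an estimated correlation and 8.52e-04 to 0.577 over all alternatives. Beside this, mitochondrial ribosomal RNA took 19.3 to 26.2% of all counts in controls and 26.9 to 29.3% in knockouts. Of 78 nuclear oxidative phosphorylation genes, Cox5a (0.74 ± 0.16, adjusted p = 0.0199) and Ndufv2 (0.47 ± 0.12, adjusted p = 0.0344) rose, 1 of them adjusted over the list alone, and none fell (camera adjusted p = 0.163, 0.0354 without control 2 and 0.0212 without knockout 4). The cytosolic ribosomal protein list was taken by gene symbol, which also takes ribosomal protein-like genes. Of its 72 tested genes the L7-like gene Rpl7l1 fell (-0.70 ± 0.15, adjusted p = 0.0176), also adjusted over the list alone, and none rose (camera adjusted p = 0.234, 0.0490 without knockout 4).

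Of 17 heat shock and proteostasis genes, the endoplasmic reticulum genes Herpud1 (0.67 ± 0.14, adjusted p = 0.0178) and Dnajb9 (0.42 ± 0.11, adjusted p = 0.0423) rose and the chaperone gene Hsph1 fell (-0.51 ± 0.11, adjusted p = 0.0235). 2 rose and 3 fell, adjusted over the list alone (camera adjusted p = 0.535). Of 24 cholesterol synthesis genes 2 rose and 4 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.163, 0.0400 without control 1 and 0.0419 without knockout 4). None of 14 cell cycle genes passed, nor any adjusted over the list alone (camera adjusted p = 0.616). Of the sex-linked list 1 gene was tested, Xist, at 199 to 306 CPM over the libraries, and 4 to 13 reads per library fell on 9 chromosome Y genes, so that all libraries read as the same sex.

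In limma's camera test with its preset correlation 12 of 39 lists were higher and 3 lower at an adjusted p of 0.05. None passed with an estimated correlation, where the lowest adjusted p was 0.0708, at an unadjusted p under 0.05 for 5 lists higher and 1 lower, and fry called 7 higher and 1 lower. Other divisions of the 8 libraries into 4 and 4 gave up to 16 camera calls in 1 direction, while they gave at most 2 genes in 1 direction.

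**Figure D5:**
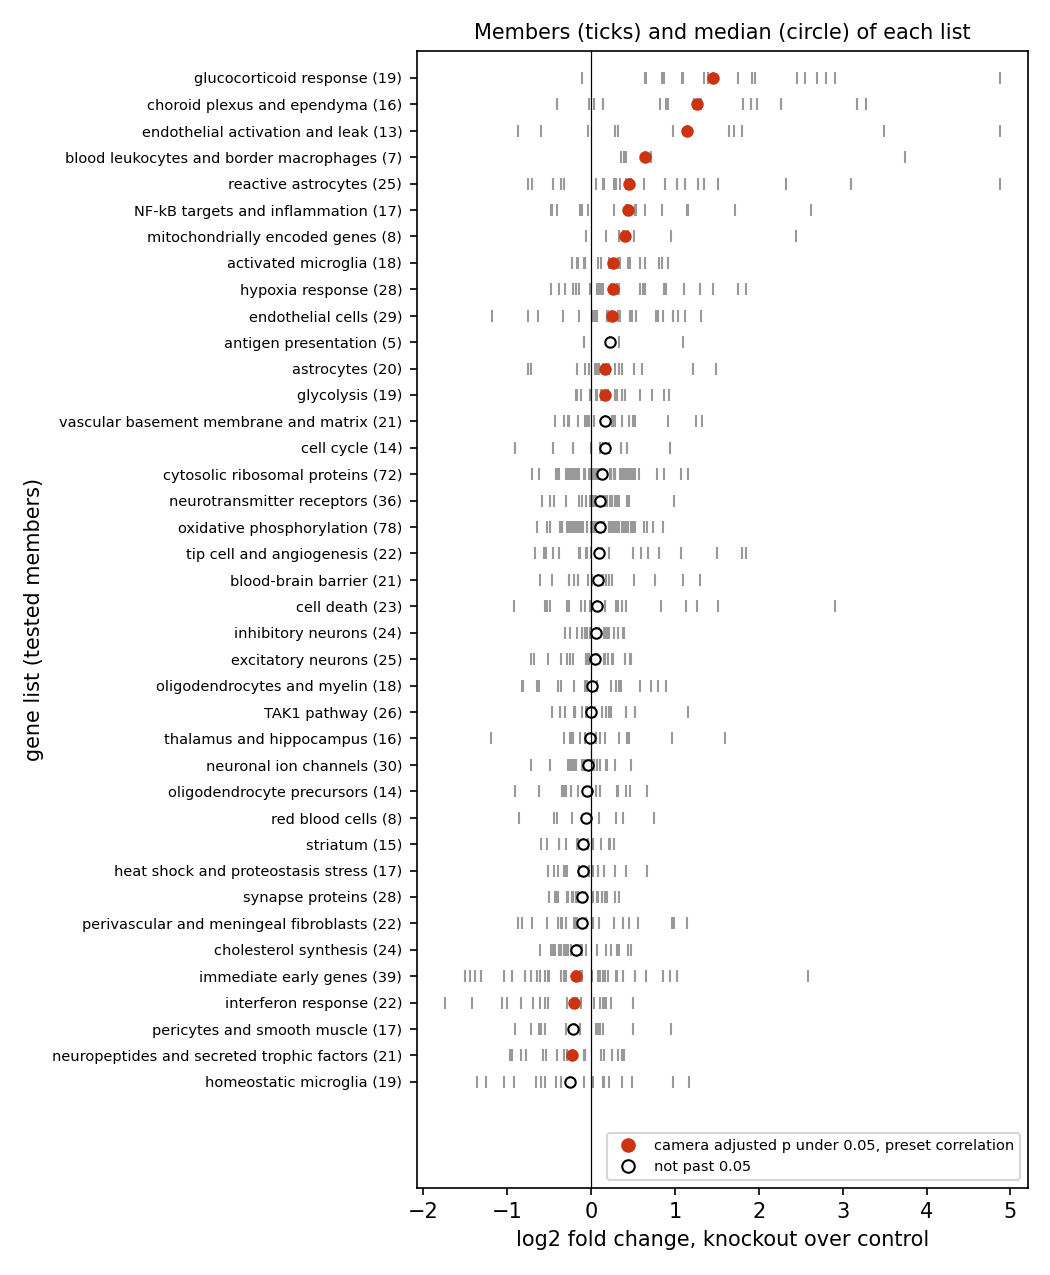
For each of 39 gene lists, grey ticks are the log2 fold changes (knockout over control) of its tested members, whose number stands in brackets, and the circle is their median. Filled red circles are the 12 higher and 3 lower lists at a camera adjusted p of 0.05 with the preset correlation and the glucocorticoid list has the highest median, 1.45.

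The libraries separated by group along the first principal component of log2 CPM, which held 36.2% of the variance. Controls lay between -41.8 and -11.0 and knockouts between 8.37 (knockout 4) and 42.4 on it, and the second component held 21.2%. Pearson correlations across genes, which are not independent replicates, were 0.969 to 0.985 within controls, 0.959 to 0.977 within knockouts and 0.950 to 0.983 between groups, the highest of the last being control 4 with knockout 4. Of nuclear ribosomal-like RNA, the gene Gm42418 took 0.669% of the counts in knockout 3 and 2.31% in knockout 5, and 0.0337 to 0.103% in the other libraries.

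The authors' deposited table holds their own DESeq2 results for the same counts. It has 1744 genes at an adjusted p of 0.05, 909 higher and 835 lower. Of the 1001 edgeR calls, 1000 were among them, all with the same sign, and log2 fold changes correlated at r = 1.000 across tested genes. The edgeR call missing there was Slc4a5.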

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

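The tests of the carried choroid plexus and ependymal tissue and of a mislabelled library were chosen only after the results were seen. In 354 sets of 4 values (1 item in 1 group), 20 had a library far from the other 3. Chance would give 17.7 for independent items. The items share the same 8 libraries, and some genes were chosen after their values were seen, so 17.7 is no fair comparison. Knockout 4 held 6 of the 20 and control 4 held 5. Knockout 4 was apart from the other knockouts for Zfp493 (1.93 CPM against 0.525 to 0.679), Edn1 (1.35 against 3.67 to 4.02), Ier5 (28.7 against 18.4 to 19.6), Bdnf (15.6 against 5.09 to 6.71), Arc (135 against 16.6 to 32.7) and Nr4a3 (54.4 against 10.9 to 16.2). Control 4 was apart for F5 (6.68 CPM against 2.16 to 2.70), Ttr (174 against 5.74 to 9.35), Gm42418 (0.103% of counts against 0.0337 to 0.0389) and the mean log2 CPM of the cell death list (2.24 against 2.01 to 2.03) and of the choroid plexus and ependyma list (1.67 against 0.75 to 0.85). Control 1 was apart for Adgrl4 (9.71 CPM against 13.5 to 14.1), Ddit4 (13.9 against 9.98 to 10.3) and Cacna1g (56.7 against 46.0 to 46.5). The others were Chn1os3 in knockout 3 (13.6 CPM against 4.61 to 5.74), Gfap in knockout 2 (239.6 against 70.7 to 94.5), and the mean log2 CPM of the neuropeptide list in control 2 (4.86 against 4.63 to 4.66), of the astrocyte list in knockout 5 (6.06 against 6.27 to 6.31), of the cell cycle list in knockout 2 (1.98 against 1.49 to 1.57) and of the oxidative phosphorylation list in control 2 (4.46 against 4.19 to 4.24).

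Choroid plexus genes were higher in knockouts, and control 4 had far more Ttr than the other controls. If tissue of the choroid plexus had been carried along in differing amounts, control 4 would be the highest control for the other choroid plexus genes, and it was for 8 of 11. Genes of a tissue move together, and control 4 had already stood apart for this list. A given control is the highest by chance 1 time in 4, so no count in this test could have decided for carried tissue. Among the controls, the mean of the list was 1.67 log2 CPM in control 4 and 0.75 to 0.85 in the others. In knockouts that mean was 2.40 to 2.47. The choroid plexus signal thus also differed between libraries of the same group. Carried tissue cannot be told apart from other causes and may account for part of these differences. Ependymal cells of the ventricle wall are argued against as the source, since the median of 4 ependymal genes was 0.0065 (range -0.41 to 0.14) against 1.56 for choroid plexus genes. An effect of the genotype on choroid plexus stays open and was not tested.

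Some activity genes of knockout 4, such as Arc and Bdnf, stood within the control range and Nr4a3 just below it (58.7 to 74.9 CPM in controls), while Ier5 (28.7 CPM against 37.0 to 52.0 in controls), Inhba (14.0 against 22.4 to 25.8) and Npas4 (7.43 against 8.43 to 13.1) also stood below every control. On 2021 genes that were called without it and tested in all libraries, knockout 4 scored 0.442 between the control mean (0) and the knockout mean (1). Controls held out in the same way scored -0.0603 to 0.391 and the other knockouts 0.821 to 1.16. Each score used its own genes, 125 to 1131 of them for the controls, so the scores do not rest on the same set. The score of knockout 4 lay above the highest control by less than the spread of the controls. By the score alone, a mislabelled control therefore cannot be told apart from a knockout with a weaker response. The mean of the glucocorticoid list in knockout 4 was 4.30 log2 CPM against 2.81 to 3.32 in controls. Knockout 4 lay above every control in 17 of 19 genes of that list. For these genes the values argue against a mislabelled control, while Arc and Bdnf do not. Bias by GC content or gene length is argued against as the whole cause, because the gap of knockout 4 over the other knockouts in the immediate early list was 0.52 (SE over genes 0.14) before and 0.56 after such a trend was removed. The gap is that of a single library, and genes of this list move together (estimated correlation 0.24). The SE over genes therefore does not measure how far the gap would vary between libraries. A difference in the state of this animal before sampling stays a possible explanation and was not tested.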

How the results depend on the processing

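The GC and length correction and the replicate block were chosen only after the results were seen. The 1001 calls (535 higher, 466 lower) became 821 and 745 without a filter, 912 and 854 in DESeq2, 1108 and 1075 at an adjusted p of 0.1, and 150 and 48 against a 1.2-fold change. Leaving out 1 library gave 93 (without control 2) to 1012 (without knockout 4) higher and 35 to 1043 lower, with fewer libraries tested in each. Upper-quartile factors gave 683 and 394. Other scalings, the stricter filter, limma voom and the GC and length correction stayed within 1.5 times. With the column number as a block over 6 libraries edgeR called 3 genes higher and 0 lower (1125 and 1177 at an unadjusted p under 0.05), and the same 6 libraries without the block gave 13 and 0. Deviations of same-numbered libraries correlated across genes at 0.01, -0.21 and 0.22, so the numbers were not taken as pairs.

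The 12 higher and 3 lower lists became 0 and 0 with an estimated correlation (5 and 1 at an unadjusted p under 0.05), 7 and 1 in fry, 0 and 0 in the exact permutation test (11 lists at its smallest p), and 6 and 3 without genes in more than 1 list. The smallest p the permutation test can give, 0.0286, was 0.101 after adjustment, so its 0 calls say little about any list. Without a filter 5 lists were lower, and leaving out 1 library gave 9 to 15 higher and 1 to 5 lower. After the GC and length correction the immediate early (camera adjusted p = 0.0706) and activated microglia (0.0651) lists lost their calls. The neuropeptide list (0.0633) lost its call with the stricter filter, and the astrocyte (0.0527) and glycolysis (0.0818) lists with the block.

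Map3k7 did not pass in any fit, at -0.093 without control 2 to 0.00013 without knockout 2. All 116 named genes that passed kept their sign in every fit. Genes that did not pass changed sign as follows, and the cause was not tested. Gfap was -0.17 without knockout 2 and up to 0.62 without knockout 3. Vegfa was -0.061 without knockout 5, 0.29 without knockout 4 and -0.0056 with the block. Kdr was -0.12 without knockout 5, -0.02 without control 4, 0.19 without knockout 4 and -0.058 with the block.

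A term for sex could not be run, since all libraries read as the same sex. Of the 35 divisions of the 8 libraries into 4 and 4, 1 (the real one) gave 535 genes or more in either direction. The real division was also the 1 that gave 466 or more, with at most 2 in any other. Every other division puts controls and knockouts in the same group, so a real group difference would widen its spread and lower its gene count. The real division was thus the most extreme of the 35 for the gene counts, but this comparison cannot exclude chance division. For lists, 5 divisions gave 12 or more and 32 gave 3 or more, with up to 16 in another division, so chance division is not excluded for the list counts.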

Other observations

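The test against the endothelial share was chosen only after the result was seen. Mitochondrial ribosomal RNA mt-Rnr1 took 1.36 to 2.18% of counts in controls and 3.03 to 4.19% in knockouts, a rise of 0.97 ± 0.17 (edgeR adjusted p = 0.00999). The more abundant mt-Rnr2 overlapped between the groups, at 17.3 to 24.0% in controls and 23.9 to 25.2% in knockouts. The cause of this difference between mt-Rnr1 and mt-Rnr2 was not tested.

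Glucocorticoid response genes were higher in every knockout library. A larger share of endothelial cells is argued against as the whole cause. The glucocorticoid list rose by 1.67 and the endothelial list by 0.27 in mean log2 CPM, a difference of 1.40 ± 0.23 (SE, n = 4 each, exact permutation p = 0.0286, the smallest possible). The glucocorticoid list already had the highest median of all lists, so this p-value is not independent evidence. Endothelial genes also moved in both directions, so their mean is a rough measure of cell share. In knockout 3 the endothelial mean was 2.63, against 2.64 to 2.77 in controls. Its glucocorticoid mean was 4.92, against 2.81 to 3.32 in controls. Sampling at another time of day cannot be told apart from the genotype by the clock genes. Genes in the phase of Dbp minus those in the phase of Bmal1 differed by -0.25 ± 0.13 (SE, n = 4 each, exact permutation p = 0.0571). Much of this came from knockout 3, at 0.54, against 0.93 to 1.11 in the other knockouts and 1.02 to 1.25 in controls. The genes in the phase of Bmal1 all had positive log2 fold changes (0.035 to 0.79), but none passed. In the phase of Dbp, Dbp (-0.56) fell while Ciart (0.78) and Hlf (0.53) rose. Each of these 3 calls was lost without control 2 or knockout 2, among others. A higher level of stress hormone in the knockout mice may be a candidate explanation, which was not tested.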
